A study of Halobacterium salinarum with 24 samples.

How the data were processed

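The series measured RNA in 24 libraries of Halobacterium salinarum, in 4 groups of 6 set by strain (parent without ura3, or without ura3 and hpyA) and salt (4.2 or 3.4 M NaCl). Per the labels' protocols, pre-cultures were diluted and the same replicates were grown at both salt levels, RNA was depleted of ribosomal RNA with manufacturer's probes for replicates 1 to 3 and with custom probes for Haloferax volcanii ribosomal RNA for replicates 4 to 6, and directional libraries were sequenced as paired ends in separate pools for these batches. Culture here means a strain and replicate number at both salt levels. Optical density at harvest was not used here.

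The authors deposited raw counts per feature, whole numbers with no normalization, for each library. FastQC, Trim Galore, cutadapt, Bowtie2, SAMtools, HTSeq and DESeq2 are named in the submitters' processing notes, with no versions. The genome build, the annotation, the strand setting and the treatment of reads that fit several places are not given in the sources used here, so no coordinates are printed, and overlapping, antisense or near-identical genes may share counts. Each library lists 2623 features and 5 summary lines of the counter, which held a mean of 6.01% of all reads (2.04% for reads in no feature) and stayed out of library sizes and tests. Of the features 292 had no count in any library. The authors' table of normalised values has 24 value columns whose names match no sample label, and these 24 columns were not used. Names come from the deposited count tables, which give a symbol for 214 features (211 of them tested). Of these symbols 205 also occur in the gene table of strain 91-R6 (assembly ASM479960v1), where arcD, ftsZ, hflX, mutS, pstA, pstB, pstC and tatC have 2 loci. The tables pair the remaining 2409 features with no name, so these are given by identifier, at most 2 higher and 2 lower per comparison.

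Ribosomal RNA was to be left out because its depletion differed between batches. Only rrf carries such a name. VNG_RS09790 and VNG_RS09800, which hold the most counts and have no line in the authors' normalised table, were left out with it. The 3 features held 87.8% of counts in batch 1 and 67.7% in batch 2. Feature counts per library summed to about 11663900 at the lowest and 149287000 at the highest, of which about 1120330 to 22602300 were used. Poisson limits cover counting error only. What the 2 unnamed features are was not given in the sources used here. hpyA was to stay out of the count of changed genes, but no feature bears that name, so none was removed.

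Counts were tested in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood test (glmQLFit and glmQLFTest) on all 24 libraries, with a mean per group and a batch term, TMM scaling and filterByExpr by group (minimum count 10, minimum total 15), which kept 2294 features. Adjusted p-values are Benjamini-Hochberg values from this test over all tested features unless another tool is named, and a feature was called changed at an adjusted p under 0.05 with no fold minimum. Fold changes are on the log2 scale. Their standard errors (SE) were derived from the edgeR test, as the absolute log2 fold change over the square root of its F statistic. They are approximate, above all for features near 0 in a group. CPM uses the TMM-scaled library sizes. The 5 comparisons are deletion against parent at each salt level, reduced against optimal salt in each strain, and the interaction, the salt change in the deletion strain minus that in the parent. This design, the rule for named genes and most lists were fixed before the data were examined.

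Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison, then with an estimated correlation and with fry. fry asks whether a list's genes move one way on balance and does not compare them with other genes. Calls of single genes adjusted over a list alone carry no correction across lists. In lists of few members they come close to unadjusted p-values. Of 40 lists, 20 with at least 4 tested members were tested. Fixed before the data were examined, and matched by symbol, were 24 lists with a tested member: ribosomal proteins, RNA polymerase, respiratory chain, gas vesicle, phototrophy and carotenoids, iron, other metal transport, phosphate uptake, purine and pyrimidine synthesis, arginine fermentation, TCA cycle, chaperones, proteasome, oxidative stress, motility, DNA replication and repair, chromatin, transcription regulators, cobalamin synthesis, cell surface and glycosylation, isoprenoid lipids, secretion and transposases. Lists fixed then without a tested member were not analysed here. Some matches do not do what the list's name says: panB stands in the proteasome list, hutU in the iron list and trmY among transcription regulators. A further 16 lists were fixed after the feature names and a first look at the values of the most abundant features and of pyrF, rrf and tnpB, and before any fold change: histidine synthesis and degradation, aromatic amino acid synthesis, glycerol use, F420, thiamine and pyridoxal, molybdopterin, amidotransferases, iron-sulfur assembly, glycine cleavage and lipoate, glycolysis, arginine metabolism, nucleoside salvage, translation enzymes and factors, cell division, and stable noncoding RNA.

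Named genes follow a rule: per comparison, the 10 called genes with the largest increase and the 10 with the largest decrease at a mean of at least 10 CPM with the same sign in both batches, and up to 2 called members with the smallest adjusted p per list fixed before the data, plus the deleted genes. Names from the 16 later lists, interaction values of single genes, arcA, arcC and arcD in optimal salt, list members whose call a block or a left-out library changed and features singled out after their values were seen fall outside the rule.

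Replicate numbers pair the salt levels within a strain, because the labels say the same replicates were grown at both. Deviations of same-numbered libraries from their group means correlated at -0.15 to 0.49 in the parent (above 0.1 in 4 of 6 pairs) and at -0.08 to 0.32 in the deletion strain (3 of 6). Across strains the numbers share only a batch, and there same-numbered pairs ran from -0.30 to 0.48 in optimal and -0.43 to 0.32 in reduced salt. These values alone thus do not show the pairing. Some parent replicates with different numbers, in different batches, correlated more: in optimal and reduced salt 1 with 4 at 0.66 and 0.59, and 3 with 5 at 0.63 and 0.70. Other such pairs ran down to -0.62. No pair of libraries held identical counts. Labels call the replicates biological, and whether they are independent was not tested.

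Alternatives were DESeq2 1.42.0 size factors and upper quartile factors, no filter, a filter of at least 10 CPM in 6 libraries, DESeq2, limma-voom, the replicate or culture as block, no batch term, each batch alone, the compared groups alone, the 3 features kept, a 2-fold minimum, and each library left out. Chosen after seeing the data were leaving out both salt levels of a culture, leaving out parent replicates 3 and 5 in reduced salt, and dropping features near 0 in the same cultures at both salt levels. Features near 0 were found in optimal salt alone, as those under 0.1 times their 0.75 quantile where that was at least 5 CPM, among 2204 features. A library or group stands apart in the closing section when Dixon's ratio, the gap of the highest or lowest of 6 log2 CPM values to the next over the range, passes its 95% critical value.

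The steps were tested on simulated data with 200 genes changed. In optimal salt the strain comparison recovered 70.1% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, with 3.39% of calls false. In reduced salt these were 62.7%, 89.6%, 98.5% and 2.91%, for salt in the parent 65.7%, 97.0%, 100% and 4.37%, for salt in the deletion strain 62.7%, 97.0%, 98.5% and 7.03%, and for the interaction 32.8%, 80.6%, 98.5% and 2.76%. A raised list passed camera in each of the 5, and 0 unchanged lists did. Simulated genes and libraries were drawn independently, with no culture effect, so this cannot show whether the preset correlation holds for the real lists. With 200 changed genes the adjusted threshold is easier to pass, so recovery can be lower in a comparison where few genes change. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.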

Results

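Halobacterium salinarum is an archaeon that lives in near-saturated brine. The data are RNA-seq counts from a parent strain that lacks ura3, a gene of uracil synthesis deleted to allow genetic selection, and from a strain that also lacks hpyA, which encodes a histone-like protein. Each strain was grown to mid-exponential phase in rich medium with 4.2 M NaCl, called optimal salt here, or 3.4 M NaCl, called reduced salt. Each of the 4 groups held 6 biological replicates, which gives 24 libraries. Replicates 1 to 3 formed batch 1 and replicates 4 to 6 formed batch 2, with different probes for the removal of ribosomal RNA and separate sequencing pools. The counts per library summed to about 11663900 at the lowest and 149287000 at the highest. After 3 features that held a mean of 77.8% of the counts were set aside, about 1120330 to 22602300 counts per library remained. The design addresses which transcripts differ when hpyA is absent, which change when salt is reduced, and whether the salt change differs between the strains.

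The deleted genes were examined first. The feature pyrF, another name of ura3, had 1 count over all 24 libraries, in a parent library at optimal salt, so no fold was computed. No feature carried the name hpyA, and which feature is that gene was not given in the sources used here. VNG_RS00550 was read in every parent library at 173 to 267 CPM (counts scaled to library size) and in the deletion libraries at 0 to 1.91 CPM. VNG_RS07805 stood at 58.2 to 156 CPM in the parent and at 3.69 to 13.1 CPM in the deletion strain. Both features were singled out after their values were seen, as the 2 whose highest deletion library lay under 0.3 times the lowest parent library. That choice used the labels, so the separation over all libraries is no check of them. With each library held out in turn, the others chose the same 2 features. By both, the held-out library lay on the side of its label in 24 of 24 cases. As both features part all 24 libraries, this outcome was fixed by their choice and is no separate check. What was not fixed is whether a further feature would be chosen that went the other way, and none was chosen.

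**Figure D1:**
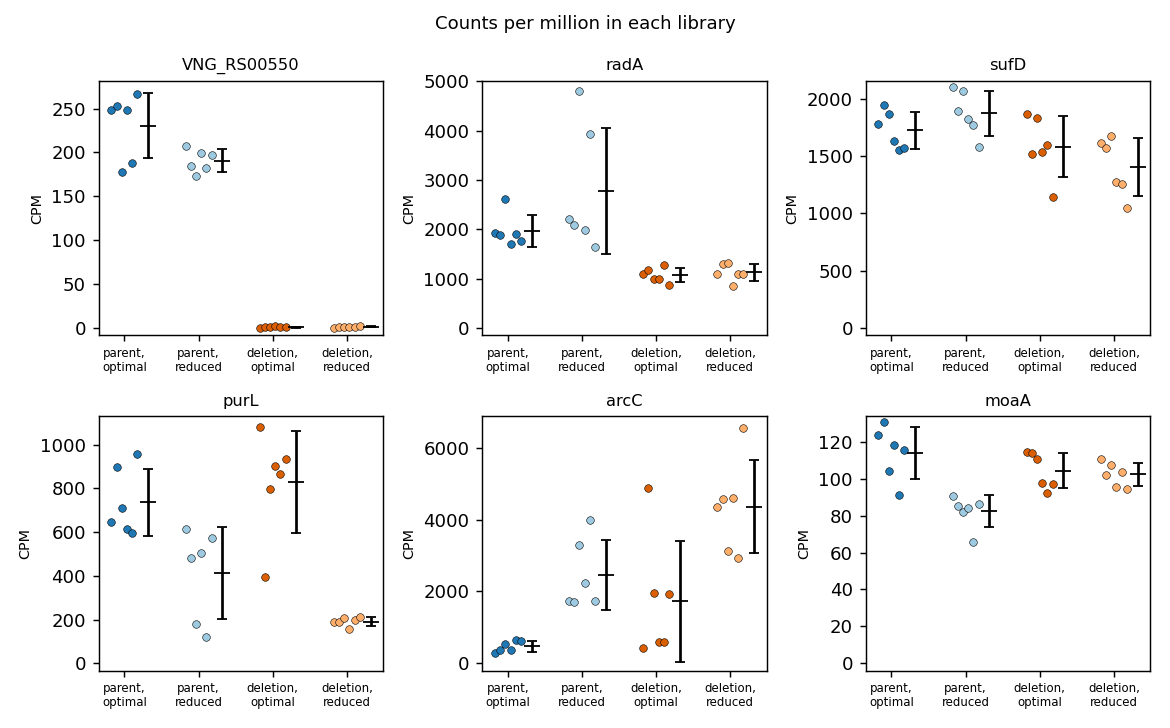
CPM of VNG_RS00550, radA, sufD, purL, arcC and moaA in each of the 24 libraries (points, by group on the x axis), with the group mean and SD (bars, n = 6). VNG_RS00550 lies between 173 and 267 CPM in the parent and at most at 1.91 CPM in the deletion strain. In parent libraries at reduced salt purL spreads from 120 to 616 CPM.

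The first principal component of log2 CPM, with the batch term removed, held 36.6% of the variance and parted the salt levels. The second held 22.6% and parted the strains, with means of 6.97 and 12.9 in the parent groups and -12.4 and -7.46 in the deletion groups. Cultures of a strain also lay apart on it. In optimal salt parent replicates 1, 3 and 4 lay at 1.61 to 2.39 and replicates 2, 5 and 6 at 11.7 to 12.0, and in reduced salt at 7.73 to 9.34 and 15.2 to 19.4. Deletion replicate 2 lay at -4.02 in optimal and 0.98 in reduced salt, beside the lowest parent value of 1.61, and the other deletion libraries at -16.8 to -6.72. Parent cultures 2, 5 and 6 and the deletion cultures other than 2 are those in which sets of 8 and 6 features, chosen after their values were seen, were near 0.

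**Figure D2:**
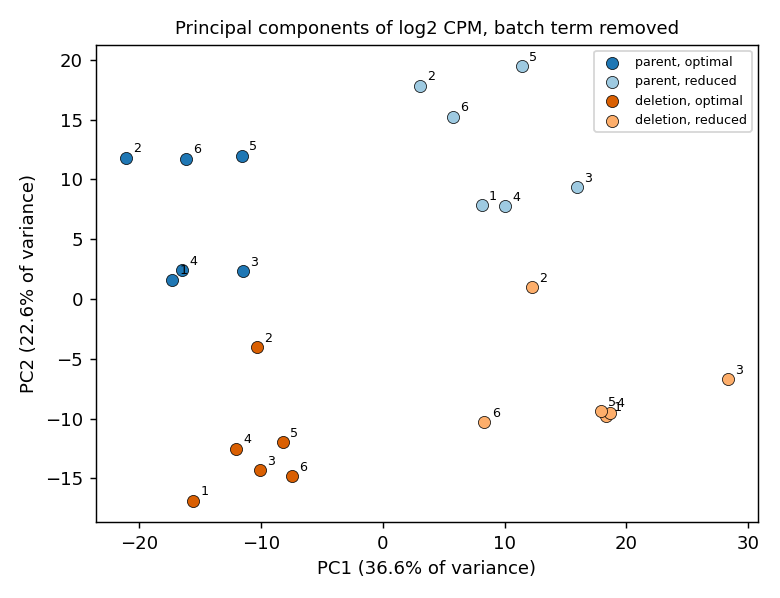
Principal components 1 and 2 of log2 CPM after removal of the batch term, 1 point per library, numbered by replicate. Optimal-salt libraries lie at negative and reduced-salt libraries at positive values of component 1, and parent libraries lie above deletion libraries on component 2, with deletion replicate 2 closest to the parent.

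Absence of hpyA in optimal salt went with a small set of changes. radA, which encodes the recombinase of homologous recombination, was the only changed gene with a name, at a log2 fold change of -0.87 ± 0.19 (SE; adjusted p = 0.0247, n = 6 per group). Its mean fell from 1968 ± 325 CPM to 1069 ± 145 CPM (SD), with differences of -0.97 in batch 1 and -0.79 in batch 2. Among features without a name, VNG_RS08405 and VNG_RS08400 rose by 0.73 ± 0.10 each (adjusted p = 6.22e-05 and 6.91e-05). VNG_RS00550 fell by 8.22 ± 0.31 and VNG_RS12920 by 4.45 ± 1.02 (adjusted p = 1.23e-15 and 0.0339). VNG_RS12920 was near 0 in 5 deletion cultures, at 0 to 0.525 CPM, and present in deletion culture 2 at 11.1 CPM, within the parent range of 8.56 to 31.4 CPM. Without deletion culture 2 its fold change was -7.28, and in batch 1 alone, which holds that culture, it was -2.26 (adjusted p = 0.632). In the DNA replication and repair list radA was the single call among 8 members, over all genes and adjusted over the list alone. The arginine fermentation genes arcA, arcC and arcD, with log2 fold changes of 0.87, 1.85 and 0.58, had 0 calls over all genes and 3 higher when adjusted over the list alone. The other 22 lists fixed before the data were examined had 0 calls either way.

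Of 2294 tested features, 16 differed between the strains in optimal salt, 6 higher and 10 lower in the deletion strain, 5 of them by at least 2-fold. At an unadjusted p under 0.05 there were 235 features, where 0.05 times the number tested is 114.7. Other splits of these libraries, balanced over batches, also passed 235, among them 1 with 546 and 1 with 386. Chance is thus not excluded for this excess. Camera passed 0 of 20 lists, as did camera with an estimated correlation and fry. The count is not stable. DESeq2 called 39 (21 higher and 18 lower), limma-voom 28, the fit with the replicate number as block 39 and a fit of these groups alone 26. Batch 1 alone gave 8 and batch 2 alone 10. Without parent replicate 6 in optimal salt the count was 56. The radA call was lost within each batch (adjusted p = 0.178 and 0.947) and in 10 of 24 fits that left out a library or a culture, where its fold stayed between -0.96 and -0.79. The VNG_RS12920 call was lost in 17 of the 24. VNG_RS08405 lost its call within each batch (adjusted p = 0.0718 and 0.0502) and VNG_RS08400 in batch 2 (adjusted p = 0.0591).

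In reduced salt the deletion strain had lower radA and, of 10 purine synthesis genes, lower purL and purD. radA fell by 1.31 ± 0.20 on the log2 scale (adjusted p = 2.70e-04), from 2779 ± 1277 CPM in the parent to 1126 ± 166 CPM, and kept its call in each of the 24 fits that left out a library or a culture. In the parent it stood at 4810 and 3932 CPM in replicates 3 and 5 and at 1649 to 2202 CPM in the others. Without those replicates the fold change was -0.82 ± 0.12. Of the 10 genes for the synthesis of purines, purL fell by 1.11 ± 0.30 and purD by 1.19 ± 0.34 (adjusted p = 0.0325 and 0.0451), 9 had negative fold changes, and 6 were lower when adjusted over the list alone. sufD, of iron-sulfur cluster assembly, fell by 0.43 ± 0.09 (adjusted p = 0.00637). moaA, of molybdopterin synthesis, rose by 0.32 ± 0.08 (adjusted p = 0.0298).

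By camera the purine list was lower in the deletion strain at reduced salt (mean log2 fold change -0.69, adjusted p = 0.0034). With an estimated correlation its adjusted p = 0.494, by fry its adjusted p = 0.103, and its call was lost in batch 2 alone (adjusted p = 0.123). The gas vesicle list, which holds the structural and regulatory genes of the gas-filled buoyancy organelle, had 12 of 12 negative fold changes with a mean of -0.34 (adjusted p = 0.0263). With an estimated correlation its adjusted p = 0.494 and by fry 0.166, none of its 12 members was called, over all genes or over the list alone, and batch 1 alone gave adjusted p = 0.495. Over all genes the other lists fixed before the data were examined had 0 calls, apart from radA among 8 DNA replication and repair genes. Adjusted over the list alone, 3 of 4 phosphate uptake genes, 2 of 2 TCA cycle genes (sucC and sucD), 1 of 3 pyrimidine synthesis genes, 1 of 5 respiratory chain genes, 1 of 2 cell surface and glycosylation genes and 1 of 2 isoprenoid lipid genes were lower, and trmY was higher. trmY is the only member of its list, so its p-value was not adjusted there (adjusted p = 0.154 over all genes). Among all 2294 features 458 had an unadjusted p under 0.05, so single members of small lists do not stand out. With the replicate block 3 of 12 gas vesicle genes and 2 of 3 pyrimidine synthesis genes were lower over the list alone.

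Of 2294 features, 92 differed between the strains in reduced salt, 34 higher and 58 lower, 27 of them by at least 2-fold. VNG_RS05130 rose by 1.56 ± 0.27 and VNG_RS05740 by 1.41 ± 0.25 (adjusted p = 0.00169 each), while VNG_RS00550 fell by 7.35 ± 0.29 (adjusted p = 3.50e-15) and VNG_RS12920 went from 35.8 ± 10.6 to 4.77 ± 11.2 CPM (SD; adjusted p = 0.00783). Again VNG_RS12920 was present in deletion culture 2, at 27.7 CPM, and at 0 to 0.45 CPM in the other deletion cultures. Its fold change was -7.57 without that culture and -2.77 in batch 1 alone (adjusted p = 0.513). DESeq2 called 167, a fit without the batch term 53, and a fit of these groups alone 37. Batch 1 alone gave 5 and batch 2 alone 17. Single libraries mattered. The count was 49 without parent replicate 1, 54 without parent replicate 4, 48 without deletion replicate 4, 49 without deletion replicate 5 and 153 without deletion replicate 6. The calls of purL and purD were lost under limma-voom (adjusted p = 0.125 and 0.151), with the replicate block (adjusted p = 0.0515 and 0.0671) and in 15 and 16 of the 24 leave-out fits. Both were also lost within each batch alone and in a fit of the compared groups alone, and that of purD without the batch term. In the parent, purL stood at 181 and 120 CPM in replicates 3 and 5 and at 483 to 616 CPM in the others. The moaA call was lost in 12 of the 24 leave-out fits. With the replicate block carB, at -1.77 ± 0.49, and nuoL, at -0.36 ± 0.10, were called lower (adjusted p = 0.0443 and 0.0362). A fit without parent replicates 3 and 5 in reduced salt called 186 features, 65 higher and 121 lower. In it purL was at -1.51 ± 0.19 and purD at -1.61 ± 0.25, 7 of the 10 purine genes were lower and the purine list kept its camera call (mean -0.99), while moaA (adjusted p = 0.0931) and the gas vesicle list (adjusted p = 0.536) lost theirs. These replicates were picked by their values, so the spread and the p-values of that fit are too small. The calls of radA, sufD, moaA, VNG_RS05130 and VNG_RS05740 were lost within each batch alone, which holds 3 replicates per group. With every replicate kept, the sufD and moaA calls were lost without the batch term. That of moaA was also lost in a fit of the compared groups alone.

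The fold changes between strains in optimal and in reduced salt correlated across the 2294 features at r = 0.728, with a covariance of 0.125. Genes are not independent replicates, and both salt levels came from the same pre-cultures. The correlation was 0.611 in batch 1 and 0.799 in batch 2. It was 0.385 between optimal salt in batch 1 and reduced salt in batch 2, and 0.514 the other way, where no culture is shared. Without the 15 features near 0 in the same cultures at both salt levels and the 2 features near 0 in the deletion strain, chosen after their values were seen, it was 0.469, and 0.128 and 0.247 across batches. Of the features called, 5 were higher and 6 lower at both salt levels, where independent lists would share 0.0889 and 0.253. With those 15 features left uncounted, 15 features differed between the strains in optimal and 88 in reduced salt, and 5 were higher and 5 lower at both, where independent lists would share 0.0895 and 0.213.

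**Figure D3:**
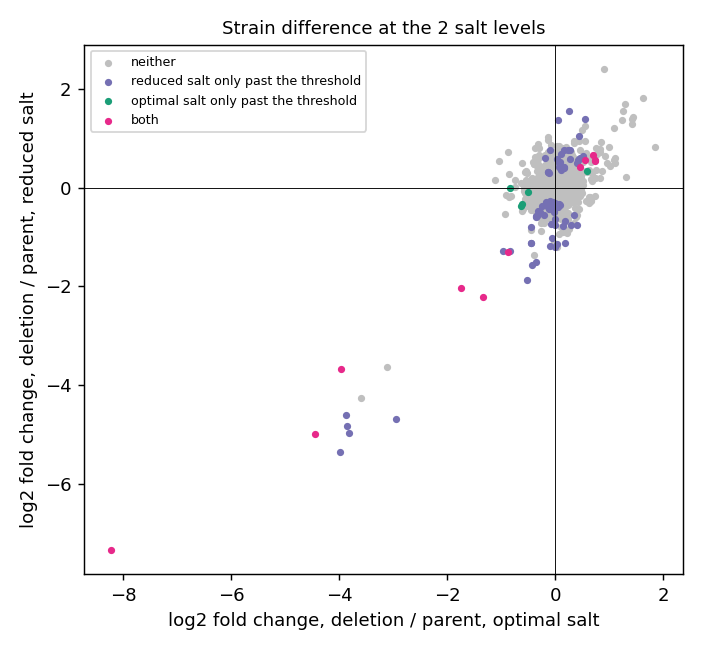
Log2 fold change of the deletion strain over the parent for each of the 2294 tested features, in optimal salt (x axis) and reduced salt (y axis), colored by whether the adjusted p passed 0.05. VNG_RS00550 lies lowest, at -8.22 and -7.35.

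Reduced salt in the parent strain raised genes of glycerol use, arginine breakdown and gas vesicles. glpK, glycerol kinase, rose by 1.41 ± 0.15 on the log2 scale (495 ± 72.8 to 1319 ± 220 CPM; adjusted p = 2.92e-07), and 3 of 3 glycerol use genes rose. arcC, carbamate kinase, rose by 2.37 ± 0.45 and argF, ornithine carbamoyltransferase, by 1.62 ± 0.30 (adjusted p = 2.40e-04 and 2.03e-04). Of the 12 gas vesicle genes 9 rose, among them gvpF by 1.20 ± 0.17 and gvpD by 1.30 ± 0.22 (adjusted p = 7.81e-06 and 6.75e-05). Of 10 purine synthesis genes 6 fell, and of 7 cobalamin synthesis genes 4 did, and with an estimated correlation the lists had adjusted p = 0.585 and 0.386. purO and purQ fell, at -1.66 ± 0.26 and -1.18 ± 0.31 (adjusted p = 2.42e-05 and 0.00338). In reduced salt parent replicates 3 and 5 had purL at 181 and 120 CPM against 483 to 616 in the others. Without these libraries, picked by their values, purL and purS lost their calls, so that 4 of the 10 purine genes fell, and guaB rose. There purQ was at -0.77 ± 0.21, the list mean was -0.42 instead of -0.72, and 6 of the 12 gas vesicle genes rose.

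Reduced salt in the deletion strain raised genes of glycerol use and lowered most of purine synthesis. glpB, a subunit of glycerol-3-phosphate dehydrogenase, rose by 2.26 ± 0.20 and glpK by 1.67 ± 0.15 (adjusted p = 1.27e-08 and 1.58e-08). Of the 10 purine genes 9 fell, with purO at -2.28 ± 0.27, purQ at -2.20 ± 0.32 and purL at -2.12 ± 0.30 (adjusted p = 8.39e-07, 7.71e-06 and 6.71e-06). carB, of carbamoyl phosphate synthesis, and acs, acetyl-CoA synthetase, fell, at -2.01 ± 0.51 and -1.98 ± 0.37 (adjusted p = 0.00262 and 1.28e-04). Without deletion replicate 3 in reduced salt carB was at -3.15, and in batch 1 alone at -1.21 (adjusted p = 0.253). gvpE rose by 1.40 ± 0.24 and cobJ, of cobalamin synthesis, fell by 0.85 ± 0.13 (adjusted p = 6.23e-05 and 1.46e-05). argF rose by 1.04 ± 0.30 and arcC by 1.35 ± 0.44 (adjusted p = 0.00668 and 0.0152). In optimal salt deletion replicate 2 stood apart from the other deletion libraries, with purL at 394 CPM against 798 to 1082, and in reduced salt deletion replicate 6 did, with glpK at 694 CPM against 1512 to 2297. Without deletion culture 4 the arcC call was lost (adjusted p = 0.0566), and batch 1 alone lost both, with argF at 0.65 and arcC at 0.69.

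In the parent, 972 of 2294 features changed with salt, 519 higher and 453 lower in reduced salt, 160 of them by at least 2-fold. In the deletion strain 1135 changed, 634 higher and 501 lower, 207 by at least 2-fold. The balance of higher and lower calls moved with the scaling: with upper quartile factors it was 458 higher and 532 lower in the parent and 561 and 567 in the deletion strain, and with DESeq2 size factors 491 and 477, and 576 and 565. Batch 1 alone gave 515 and 753, batch 2 alone 375 and 471. Of the calls, 430 higher and 338 lower were shared, where independent lists would share 143 and 98.9, and 1 went opposite ways. The fold changes correlated across genes at r = 0.862. The strains share no library. The largest changes were in features without a name. VNG_RS07480 rose by 2.71 ± 0.39 in the parent and by 2.93 ± 0.39 in the deletion strain, VNG_RS09535 rose by 2.66 ± 0.44 in the parent and VNG_RS07140 by 3.06 ± 0.42 in the deletion strain. VNG_RS05265 and VNG_RS11475 fell by 2.39 ± 0.34 and 2.07 ± 0.23 in the parent, and VNG_RS08195 and VNG_RS03425 by 2.49 ± 0.32 and 2.46 ± 0.33 in the deletion strain.

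Camera passed 4 lists for salt in the parent. Gas vesicle genes were higher (adjusted p = 0.0144), and purine synthesis (0.0256), other metal transport (0.0256) and cobalamin synthesis (0.0467) were lower. With an estimated correlation these were adjusted p = 0.527, 0.585, 0.386 and 0.386. The members of the metal list are cbiG, cbiQ and cbiT, which belong to cobalamin synthesis or its cobalt supply and stand in the cobalamin list too, and arsD of arsenic resistance. In the deletion strain 3 lists passed, all lower: purine synthesis (adjusted p = 9.76e-05), cobalamin synthesis (0.00515) and other metal transport (0.0219). With an estimated correlation these were adjusted p = 0.315, 0.230 and 0.315. Gas vesicle genes, with 7 of 12 higher, had adjusted p = 0.0573. Without parent replicates 3 and 5 in reduced salt, picked by their values, none of the 4 parent lists passed (adjusted p = 0.0743 for gas vesicle and metal transport and 0.108 for purine and cobalamin synthesis), and 763 features changed. Of 68 list members called in the parent 23 lost their call in that fit and 3 were added. Isoprenoid lipid synthesis, aromatic amino acid synthesis, ribosomal proteins, the respiratory chain and transposases were left with 0 calls, molybdopterin synthesis, glycolysis, histidine synthesis and arginine fermentation with 1 each, and nucleoside salvage and histidine degradation with 2 each. radA, called at 0.50 with all libraries, was at 0.01 ± 0.12. The cobalamin call in the parent was lost in batch 1 (adjusted p = 0.114) and the metal call in the deletion strain in batch 2 (adjusted p = 0.0527).

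**Figure D4:**
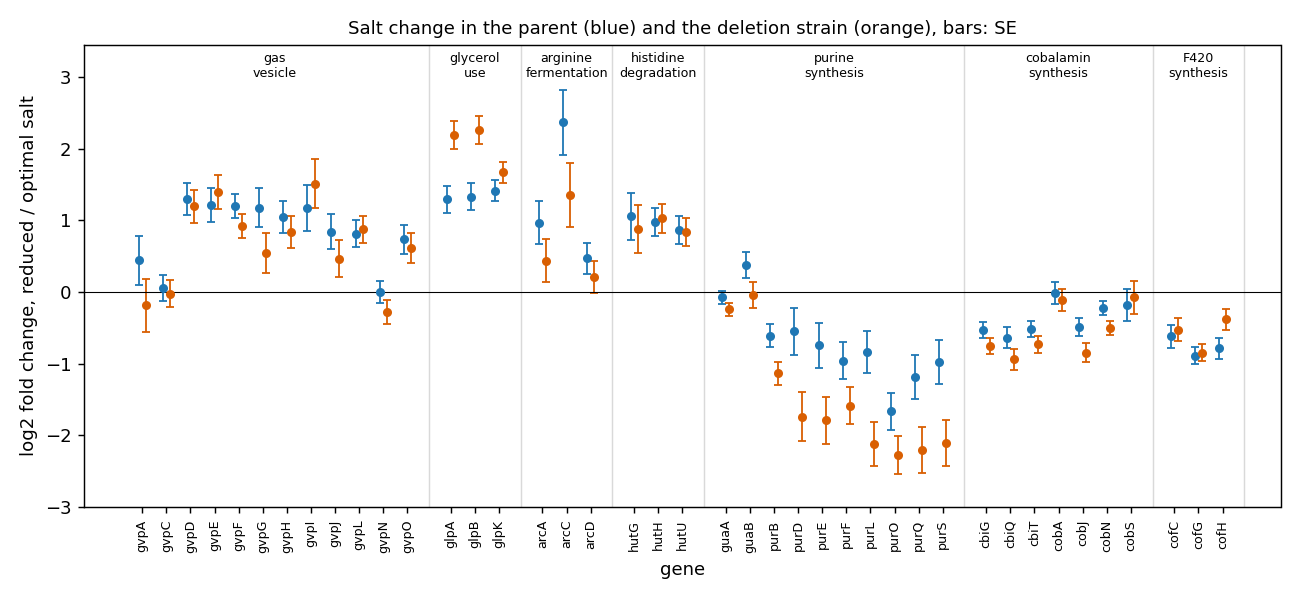
Log2 fold change of reduced over optimal salt for the members of 7 gene groups, in the parent (blue) and the deletion strain (orange), with SE as bars (n = 6 per group). glpK lies at 1.41 and 1.67, and purO at -1.66 and -2.28.

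Smaller groups also had members that changed with salt, given here as parent and then deletion strain. Of all tested features 42.4% and 49.5% were called, higher or lower. Here and in the paragraphs that follow, lists with about that share called do not stand out from other genes. Adjusted over the list alone the counts were the same unless given. Histidine degradation rose in 3 of 3 genes in both strains, with hutH at 0.98 and 1.03. F420 synthesis, which makes a deazaflavin cofactor, fell in 3 of 3 genes in both, with cofG at -0.89 and -0.84. Purine synthesis fell in 6 of 10 (7 over the list alone) and 9 of 10, and cobalamin synthesis in 4 of 7 (5 over the list alone) and 5 of 7. Metal transport fell in 4 of 4 and 3 of 4. Arginine fermentation rose in 2 of 3 (3 over the list alone) and 1 of 3, and arginine metabolism in 4 of 6 (5 over the list alone) and 3 of 6, with 1 lower in each. argH rose by 2.47 ± 0.54 in the parent. Glycerol use rose in 3 of 3 in both. Phosphate uptake had pstB higher in both, at 0.89 and 0.97, and 3 of 4 members lower in the deletion strain, with phoU at -0.67. pstB, like pstA, pstC, arcD, ftsZ, mutS and tatC, has a second locus of its name in the gene table. Counts of these genes, and with them the phosphate uptake values, are uncertain where reads were shared. Pyrimidine synthesis fell in 0 of 3 and 2 of 3. In the 24 fits that left out a library or a culture, the parent calls of purL were lost in 4 and those of purS, arsD and hutG in 1 each (highest adjusted p = 0.0687, for purL). In the deletion strain those of hutG were lost in 10, of cofH and guaA in 8 each, of gvpO and pyrB in 6 each, of argH in 5 and of arcC in 1 (highest adjusted p = 0.136, for cofH), and argH, at 1.62, ranged from 0.97 to 2.11. With the culture as block no list member lost a call for salt over all genes. In the parent 10 more were called, with arcD, ftsZ and trpD higher and carB, dnaK, nuoL, purE, pyk, rpmC and secY lower, purE at -0.95 ± 0.32 (adjusted p = 0.0258). In the deletion strain 6 more were called, with arcA higher at 0.70 ± 0.23 (adjusted p = 0.0181) and carA, ftsY, metG, ppsA and rpmC lower. Arginine fermentation then rose in 3 of 3 and 2 of 3 genes, and purine synthesis fell in 7 of 10 and 9 of 10.

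None of the lists that follow passed camera, or they had under 4 members and were not tested. DNA replication and repair had 2 higher and 4 lower of 8, then 1 higher and 3 lower, with mutS at -0.45 and -0.51 and gyrA at -0.36 and -0.39. Of the chromatin list gyrA and gyrB fell in both strains, 2 of 3, though without deletion culture 4 gyrB lost its call in the deletion strain (adjusted p = 0.0519). Chaperones fell in 1 of 2 (2 over the list alone) and 2 of 2, with dnaJ at -0.75 and -0.56. The proteasome list fell in 1 of 4 in both, psmA at -0.47 and -0.43. Ribosomal proteins fell in 1 of 4 and 2 of 4, the respiratory chain in 1 of 5 and 2 of 5, and the TCA cycle in 0 of 2 and 2 of 2. Isoprenoid lipid synthesis fell in 2 of 2 in both, secretion in 1 of 2 (2 over the list alone) and 2 of 2, and cell surface and glycosylation in 1 of 2 in both, aglJ at -0.62 and -0.52. Oxidative stress genes rose in 0 of 3 and 2 of 3. Of lists with 1 member, crtI (phototrophy and carotenoids) and hutU (matched by the iron list, though it degrades histidine) rose and tnpB (transposases) fell in both, trmY (transcription regulators) rose in the deletion strain, and flaJ (motility) was not called. RNA polymerase had 0 of 2 called in both. In the 24 leave-out fits the parent calls of radA were lost in 13, of mvaD and hmgA (isoprenoid lipids) in 7 and 5, of rpmD (a ribosomal protein) in 3, of tnpB in 2 and of coxB (respiratory chain) in 1, with adjusted p up to 0.194 for radA, 0.0831 for hmgA and 0.0814 for mvaD. The calls of mvaD and hmgA were lost within each batch alone too. In the deletion strain those of msrB (oxidative stress) were lost in 20, of crtI in 16, of coxB and rpl4p (a ribosomal protein) in 10 each, of tnpB in 6, of msrA in 3, of dnaK in 2 and of gyrB in 1, with adjusted p up to 0.183 for msrB, 0.154 for coxB and 0.170 for rpl4p. The crtI and msrB calls there were also lost under 9 and 11 of 12 alternatives, other scalings among them. Without the batch term hmgA, rpmD and tnpB lost their calls in the parent and rpl4p and tnpB in the deletion strain.

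Of the lists fixed after feature names were read, nucleoside salvage fell in 4 of 5 and 3 of 5 (4 over the list alone, though 3 with the block), glycolysis in 2 of 5 in both (3 over the list alone in the parent), histidine synthesis in 2 of 6 in both and molybdopterin synthesis in 3 of 4 and 1 of 4. Aromatic amino acid synthesis rose in 2 of 6 and 4 of 6, with 1 lower in the deletion strain. Thiamine and pyridoxal synthesis rose in 1 of 5 in both, thiC at 0.71 and 0.85. Translation enzymes and factors had 1 of 10 lower in both and 1 higher in the deletion strain (0 higher over the list alone), with aspS at -0.73 and -0.77. Amidotransferases had 1 of 5 lower in both and 1 higher in the parent. Glycine cleavage and lipoate genes fell in 0 of 4 and 2 of 4. Iron-sulfur assembly (2 genes), cell division (4) and stable noncoding RNA (2) had 0 calls. In the 24 leave-out fits the parent calls of deoC were lost in 13, of aroA in 9, of gatE and moeB in 8 each, of hisF in 7, of mobB in 5 and of eno in 4 (adjusted p up to 0.116, for aroA). In the deletion strain those of thrS (a threonyl-tRNA synthetase) were lost in 18, of trpE in 14, of pheA in 13, of trpD in 10, of tpiA in 9, of aroA in 6 and of deoC in 2 (adjusted p up to 0.247, for thrS). The thrS call was also lost under 10 of 12 alternatives, other scalings among them. The aroA call was lost without the batch term in both strains and with upper quartile factors in the parent, and eno and gatE in the parent and lipA in the deletion strain lost theirs without the batch term.

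The salt change itself was compared between the strains as an interaction, as the log2 change in the deletion strain minus that in the parent, so that a negative value means a larger fall or a smaller rise in the deletion strain. Purine synthesis genes, with mean salt changes of -0.72 in the parent and -1.52 in the deletion strain, had 10 of 10 negative values with a mean of -0.80, purL at -1.28 and purB at -0.53, though no single gene was called over all genes, and 6 were lower when adjusted over the list alone. With the culture as block 0 of the 10 were lower, over all genes or adjusted over the list alone, with purL at -1.04 ± 0.37 (unadjusted p = 0.0128). Of the other lists fixed before the data were examined, 2 of 2 TCA cycle genes were lower when adjusted over the list alone, and with the block so were 3 of 4 phosphate uptake, 3 of 3 pyrimidine synthesis and 1 of 2 isoprenoid lipid genes. Phosphate uptake had a mean of -0.43, cobalamin synthesis -0.19, and glycine cleavage and lipoate -0.21. By camera the adjusted p was 1.19e-04 for purine synthesis and 0.0431 for each of the others. With an estimated correlation the adjusted p = 0.544, 0.655, 0.544 and 0.544, and fry passed 0 lists. The glycine cleavage call was lost with the culture as block (adjusted p = 0.0687) and without parent replicates 3 and 5 in reduced salt (adjusted p = 0.0809). In batch 1 alone phosphate, cobalamin and glycine lost their calls, and in batch 2 alone cobalamin and glycine did.

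For single features the interaction gave 0 calls of 2294 by edgeR. At an unadjusted p under 0.05 there were 209, where 0.05 times the number tested is 114.7. Of 100 splits of the cultures, the real one included, 5 gave at least 209, so chance is not excluded. limma-voom gave 0 and DESeq2 17 (3 higher and 14 lower). With the culture as block 5 passed, among them glpB at 0.91 ± 0.16 (adjusted p = 0.0396), and batch 1 alone gave 3. Leaving out parent replicate 6 in optimal salt gave 14, and parent replicate 6, deletion replicate 1 and deletion replicate 6 in reduced salt gave 1 each, and deletion replicate 3 in reduced salt 2. Without parent replicates 3 and 5 in reduced salt, picked by their values, 25 passed, 6 higher and 19 lower, among them 5 purine genes, all lower, with purL at -1.68 ± 0.26 (adjusted p = 0.00123). On simulated counts, drawn without culture effects, this contrast recovered 32.8% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes.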

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

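All tests of explanations in this part were chosen after the results they weigh were seen, while the comparison of splits was planned as a check and its prediction written after the counts were known.

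Of 348 groups of 6 values of named genes, library sizes and set-aside shares, 31 held a library that stood apart from the other 5 by Dixon's ratio on log2 CPM. Chance gives about 1 in 20, or 17.4, if groups are independent. They share libraries and related genes, so the excess was not tested. Deletion replicate 6 in reduced salt held 9 of them: aglJ (ratio 0.714), cofG (0.694), glpK (0.650), lpdA (0.779), sucC (0.629), sucD (0.646), thiC (0.653), thrS (0.628) and VNG_RS07480 (0.667), with glpK at 694 CPM against 1512 to 2297 and thiC at 1555 against 3437 to 5236. Without this library 153 features differed between strains in reduced salt instead of 92. Deletion replicate 2 in optimal salt held 6: carB (0.719), purD (0.845), purL (0.698), purO (0.791), purS (0.698) and VNG_RS12920 (0.696), with purL at 394 CPM against 798 to 1082. The same culture stood apart at reduced salt for VNG_RS12920 (0.775) and cdd (0.690). Deletion replicate 3 in reduced salt was low for hisD (0.824) and speB (0.682), and deletion replicate 4 in optimal salt for glpB (0.698). In the parent at optimal salt these were cbiT in replicate 5 (0.692), gvpD and msrA in replicate 2 (0.673 and 0.637), gvpE, ndk, radA and VNG_RS12920 in replicate 3 (0.668, 0.653, 0.709 and 0.736) and purS in replicate 6 (0.633). In the parent at reduced salt they were hutH in replicate 2 (0.811) and moaA and pyrB in replicate 5 (0.679 and 0.714).

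Differences between the strains in their salt change were found by camera for purine synthesis (mean -0.80), phosphate uptake (-0.43), glycine cleavage and lipoate (-0.21) and cobalamin synthesis (-0.19). None held with an estimated correlation. The 3 features left out of the tests held a mean of 77.8% of the counts, a signal outside the comparisons.

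A set of features was near 0 in some cultures and not in others of the same strain. Of 18 found in optimal salt, 15 were near 0 in the same cultures in reduced salt: 6, VNG_RS12920 among them, in deletion cultures 1, 3, 4, 5 and 6, 8 in parent cultures 2, 5 and 6, and 1 in parent culture 2. Low depth is argued against, since the upper 95% Poisson limit reached the lowest value of present libraries in 4.39% of 114 near-0 pairs. Parent RNA in deletion culture 2 is argued against too. There VNG_RS00550, among 9 features that part the strains in the other 22 libraries, stood at 0.501% of the parent mean at most. VNG_RS07805 stood at 6.33% and 10.2%, while the 6 features had medians of 70.2% and 77.7%. The remaining feature, VNG_RS14110, no longer parted the strains by the factor of 0.3 once that culture was counted. A trait carried by each culture from its pre-culture stays open: of 216 feature and culture pairs 212 were alike at both salt levels, and 48 of 1296 permutations of culture numbers within strain and batch did as well (exact p = 0.0370, the smallest these patterns allow). Lost DNA and inherited silence may each give this pattern and were not told apart by any value here.

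In the parent at reduced salt purL stood at 181 and 120 CPM in replicates 3 and 5 and at 483 to 616 CPM in the others, purD at 157 and 101 CPM against 452 to 537, and radA at 4810 and 3932 CPM against 1649 to 2202. A mislabelled deletion library is argued against by the 2 features that part the strains in the other 22 libraries: of the mean of the other parent libraries in reduced salt, VNG_RS00550 stood at 87.6% and 92.3% in replicates 3 and 5, and VNG_RS07805 at 239% and 223%, above its level in any other parent library. The depletion batch is argued against too, since batch 1 ran from 181 to 616 and batch 2 from 120 to 572 CPM. A difference in growth stage at harvest could give such a spread and stays open, as optical density per culture was not used here. Parent replicates 3 and 5 lay apart in optimal salt too, at -11.5 and -11.6 on the first principal component against -21.1 to -16.2. In reduced salt they lay at 15.9 and 11.4 against 3.01 to 10.1. On the second component they were not alike, at 2.32 and 12.0 in optimal salt. The fits without them in reduced salt kept their optimal-salt libraries.

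Other splits of the same libraries were tested for each count. In optimal salt 6 of 100 splits balanced over batches gave at least the real 16 features between strains, and the highest other gave 116, several times the real count, which points to a structure of the samples. Chance is not excluded there. In reduced salt 2 of 100 gave at least 92, the real one included. That is under 5 in 100, a level written after the counts were known. A split that mixes the strains did as well, so chance is argued against but not excluded. The highest other, with 94, set parent replicates 3 and 5 with deletion replicates 1, 3, 4 and 5. For salt, 1 of 32 splits that part every pair, the real one, gave as many in the parent (972, highest other 235). In the deletion strain it was 1 of 32 too (1135, highest other 707). Chance is argued against in both. Splits that keep fewer pairs apart reached 478 and 658. For the interaction 100 of 100 gave at least 0 (highest other 14). At an unadjusted p under 0.05, 5 of 100 gave at least 209 (highest other 374), so chance is not excluded. With the culture as block 4 of 100 gave at least 5 (highest other 16). Only this interaction count fell under 5 in 100, a level written after the counts were known, so chance is not excluded there either.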

How the results depend on the processing

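Leaving out both salt levels of a culture or parent replicates 3 and 5 in reduced salt, dropping near-0 features and leaving out libraries in the correlation were chosen after seeing the data, and the other alternatives before. No named gene and no list that passed camera changed direction under any alternative. Without parent replicates 3 and 5 in reduced salt, means of some lists that had not passed changed sign. For gas vesicle genes in the interaction the mean went from -0.18 to 0.09. No scaling moved the median log2 fold change by over 0.1. The analysis of the authors' normalised values was not run, as no column matched a sample label. Causes were not tested except where fewer libraries were used.

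Between strains in optimal salt, 16 features became 39 with DESeq2, 28 with limma-voom, 39 with the replicate block, 8 in batch 1, 10 in batch 2, 26 with the compared groups alone and 5 at 2-fold. Leaving out a library or culture gave 12 to 56. In reduced salt 92 became 167 with DESeq2, 53 without a batch term, 5 in batch 1, 17 in batch 2, 37 with the compared groups alone and 27 at 2-fold, and leaving out gave 41 to 170. Salt gave 515, 375 and 160 in the parent and 753, 471 and 207 in the deletion strain in batch 1, in batch 2 and at 2-fold, and 809 to 1043 and 933 to 1176 when leaving out. The interaction gave 17 with DESeq2, 5 with the block, 3 in batch 1 and 0 to 14 when leaving out. The block, which is the replicate number across strains and the culture for salt, gave 115 in reduced salt, 1086 and 1212 for salt, and changed no other count by over 1.5 times. It ended the calls of purL and purD between strains in reduced salt and of the glycine cleavage list in the interaction, and no other call of a named gene over all genes or of a list by camera. The 6 purine genes lower in the interaction over the list alone became 0. It added list members: 2 between strains in reduced salt, 10 and 6 for salt and 1 in the interaction. Without parent replicates 3 and 5 in reduced salt, 186 features differed between strains there, 763 changed with salt in the parent and 25 in the interaction, and 4, 0 and 3 lists passed camera. Not counting near-0 features gave 15 and 88 between strains and left 972 and 1135 for salt. Across strains the numbers share only a batch: 2 of 6 pairs in optimal and 2 of 6 in reduced salt correlated best with their own number.

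Of the named genes for salt, 17 in the parent and 20 in the deletion strain lost their call in batch 1 alone and 25 and 27 in batch 2 alone, and at most 6 did under any other setting that kept every replicate.

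Lists passing camera fell to 0 with an estimated correlation in each comparison. By fry, 1 list passed between strains in reduced salt, neither of the 2 that passed camera, 10 and 15 for salt in parent and deletion strain, among them the 4 and 3 that passed camera, and 0 of 4 in the interaction. In batch 1 and batch 2 alone 1 list each passed between strains in reduced salt, and 1 in batch 1 for the interaction.

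The correlation of strain effects, 0.728, was 0.611 in batch 1, 0.385 and 0.514 across batches, 0.469 without near-0 features and then 0.128 and 0.247 across batches. Leaving out a library gave 0.663 to 0.746. Batch 1 libraries held about 1120330 to 16858300 counts after exclusions and batch 2 libraries 6229940 to 22602300.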

Other observations

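Both comparisons of this part were chosen after the values were seen. The arginine genes varied between cultures of the deletion strain in optimal salt. arcC, carbamate kinase, ran from 433 to 4870.1 CPM in the 6 deletion libraries and from 286 to 650.1 CPM in the 6 parent libraries at optimal salt, with means of 1730 and 473 CPM. argF, ornithine carbamoyltransferase, had means of 4162 ± 2933 and 2026 ± 313 CPM (SD). Neither gene was called between strains (adjusted p = 0.0525 and 0.131 by edgeR for arcC and argF).

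The interaction values of the glycerol genes, the salt change in the deletion strain minus that in the parent, were 0.90 ± 0.27 for glpA, 0.94 ± 0.26 for glpB and 0.25 ± 0.20 for glpK (SE). Over all genes none was called (adjusted p = 0.220, 0.207 and 0.777), and 2 of the 3 passed when adjusted over the list alone. With the culture as block glpB was called, at 0.91 ± 0.16 (adjusted p = 0.0396), and glpA and glpK were not (adjusted p = 0.0997 and 0.701). Without parent replicates 3 and 5 in reduced salt, picked by their values, glpA and glpB were called, at 1.18 ± 0.25 and 1.14 ± 0.27 (adjusted p = 0.0124 and 0.0333).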
